A study of Mus musculus with 18 samples.

How the data were processed

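Gene expression was measured in mPAC L20 cells, a mouse pancreatic duct cell line, on 18 Affymetrix mouse genome arrays. The arrays fell into 6 groups of 3: uninfected cells, cells given an adenovirus coding for β-galactosidase (Bgal), for mouse Atoh8 (Atoh8) or for human Neurogenin 3 (Ngn3), and cells given a pair of viruses (Bgal+Ngn3 and Ngn3+Atoh8). Per the labels' protocols, 250000 cells were seeded, each virus was used at a multiplicity of infection of 40 for 2 h, and culture went on for a further 44 to 46 h. Groups and replicate numbers were taken from the sample titles, and the whole experiment was performed 3 independent times per the series description. Total RNA was converted to biotin-labelled cRNA before hybridization, per the labels' protocols.

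The deposited table holds log2 values made by the authors with RMA, which corrects background, normalizes arrays together and summarises the probes of a probe set; per the submitters' processing notes the tools were RMA and affy, and their versions are not given in the sources used here. The table has 45101 probe sets, of which 64 are array controls. The median of an array lay between 5.90 and 5.99 log2 units. The 3' minus 5' difference of the array's beta-actin controls was -0.0026 to 0.150 log2 units and that of its Gapdh controls -0.134 to -0.063. Arrays have no read depth, so 3 arrays per group set the precision. A low value on the RMA scale was not tested against background, because the table carries no detection calls.

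Probe sets were named from a platform annotation table, checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and was used for names only. A single symbol was given for 34945 probe sets, 932 carried several symbols and were left out, and 9160 others were unnamed here and were left out of tests by gene. Each of the 18193 genes tested was represented by the probe set with the highest mean over all arrays; 9010 genes had more than 1 probe set. The most similar pair of arrays had a correlation of 0.998 and a median absolute difference of 0.082 log2 units, so no array was a copy of another.

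Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes) in 1 fit of all 18 arrays with 1 coefficient per group. Adjusted p-values are Benjamini-Hochberg values within a comparison, and a gene was called at an adjusted p under 0.05 with no fold minimum. The 6 comparisons were Bgal minus uninfected, Bgal+Ngn3 minus Ngn3, Atoh8 minus Bgal, Ngn3 minus Bgal, Ngn3+Atoh8 minus Bgal+Ngn3, and the difference between the effects of Atoh8 with and without Ngn3. Gene lists (21, each with at least 5 measured members) were tested with limma's camera at its preset correlation of 0.01, adjusted over lists within a comparison. The camera test was repeated with an estimated correlation, and fry, a directional test of a list by itself, was run as well. The samples' groups, the tests, the lists, the rule for named genes and the other fits listed below were all fixed before the data were examined.

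The genes named were Atoh8 and Neurog3, the 8 largest rises and 8 largest falls among called genes whose 3 arrays of one group lay all above or all below the 3 of the other, up to 4 called members of each list by size of change, and in comparisons with no call the 3 genes with the smallest p. Predicted genes without a curated symbol were skipped among the largest rises and falls. Where other genes are named, they were chosen after their values were seen. The lists of genes called for Ngn3 were tested in Ngn3+Atoh8 minus Bgal+Ngn3, which shares no array with Ngn3 minus Bgal. The same was planned for genes called for Atoh8 and for infection.

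Replicate numbers paired the arrays. The experiment was repeated as 3 independent runs per the series description. The deviations of same-numbered arrays from their group means correlated at 0.19 to 0.68, against a median of -0.22 for arrays of different number. Deviations from a group mean cancel within the group, so the negative median follows from the positive values and is no separate evidence. Each of the 18 arrays correlated best with an array of its own number. Fits chosen alongside were one with the replicate number as a block, and ones with quantile normalization, median centring, leaving out the dimmest 40% of genes, testing all probe sets, fitting only the compared groups, a trended and robust variance, a fold of at least 1.5, other control arms and leaving out arrays or whole replicates. A covariate for the Neurog3 signal, the estimated correlation and fry with a block, and list tests with arrays left out were added after the data were seen.

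The procedure was tested on simulated data built from the observed gene means and spreads, with 200 of 18193 genes changed in each of 5 sets. For Atoh8 minus Bgal, 12.4% of genes changed 1.25-fold were called, 71.2% at 1.5-fold, 95.6% at 2-fold and 100% at 4-fold, and 0.8 unchanged genes were called per set. With the block these shares were 38%, 90.8%, 99.2% and 100%, with 10 unchanged genes called per set. For Ngn3 minus Bgal they were 14.8%, 72%, 94.4% and 100% without the block. Each simulated replicate shifted a gene equally in all groups, and the noise had the size left after blocking, the same in every group. This setting favours the block. The rates do not describe genes whose replicate differences or spread vary between groups. A list of 25 genes shifted by 0.2 log2 units was called in 20 of 20 simulated sets, and an unshifted list in 1 of 20. The members of these lists were drawn at random and given independent noise. Those rates therefore do not describe gene lists whose members move together.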

Results

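The 18 arrays of mPAC cells, a line derived from mouse pancreatic duct, comprised 3 biological replicates of uninfected cells and of each of 5 infections. On the deposited log2 scale, component 1 of a principal component analysis held 60.0% of the variance and set the 9 arrays given the Ngn3 virus apart from the other 9. Component 2 held 10.7% and set replicate 3 apart from replicates 1 and 2 in every group.

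**Figure D1:**
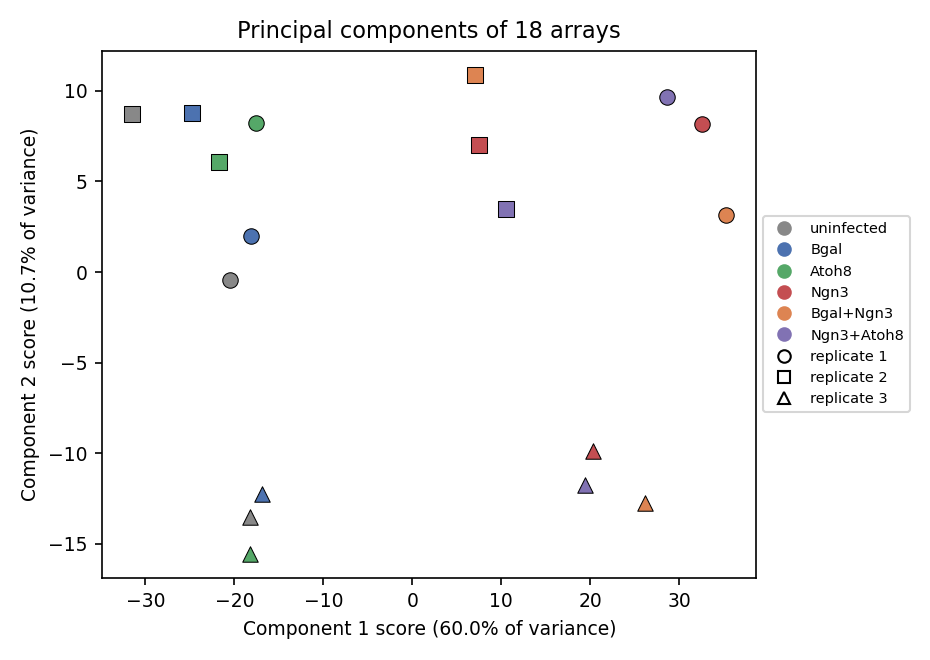
Scores of the 18 arrays on components 1 and 2 (axes in score units, with the share of variance), coloured by group, with circles, squares and triangles for replicates 1, 2 and 3. The 9 arrays with Ngn3 lie at component 1 scores of 7.06 to 35.3, and the others lie below 0.

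Neurog3, the transcription factor that starts endocrine differentiation in the pancreas, stood at 8.41 ± 1.30 log2 units in Ngn3 arrays (SD, n = 3) and 5.52 ± 0.21 in Bgal arrays on the brighter of its 2 probe sets. This is a rise of 2.89 ± 0.60 (SE; limma adjusted p = 0.00446), and the other probe set rose by 3.82 ± 0.65. The value was highest in replicate 1, at 9.89 in Ngn3, 9.67 in Bgal+Ngn3 and 8.17 in Ngn3+Atoh8. Neurog3 was 1.18 log2 units lower in Ngn3+Atoh8 than in Bgal+Ngn3 (-1.18 ± 0.60, adjusted p = 1.00), lower in 3 of 3 replicate pairs, and the other probe set differed by -1.57 ± 0.65. The virus carries the human cDNA and the probe sets were designed for mouse, so the transgene and the cells' own transcript cannot be separated.

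Atoh8, a basic helix-loop-helix factor, had 1 probe set. It stood at 6.83 ± 0.19 in arrays labelled Atoh8 (SD, n = 3), 6.86 ± 0.03 in Bgal and 6.65 ± 0.13 in uninfected arrays, so it was no higher in cells given the Atoh8 virus (-0.03 ± 0.09, adjusted p = 0.998). It rose by 1.27 ± 0.09 with Ngn3 (adjusted p = 6.05e-07). In Ngn3+Atoh8 it was 8.02 ± 0.02 against 8.31 ± 0.09 in Bgal+Ngn3 (-0.29 ± 0.09, adjusted p = 1.00). Where this probe set lies relative to the cDNA in the virus is not known, so it does not check the label, and every direction drawn for Atoh8 below rests on the label alone.

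**Figure D2:**
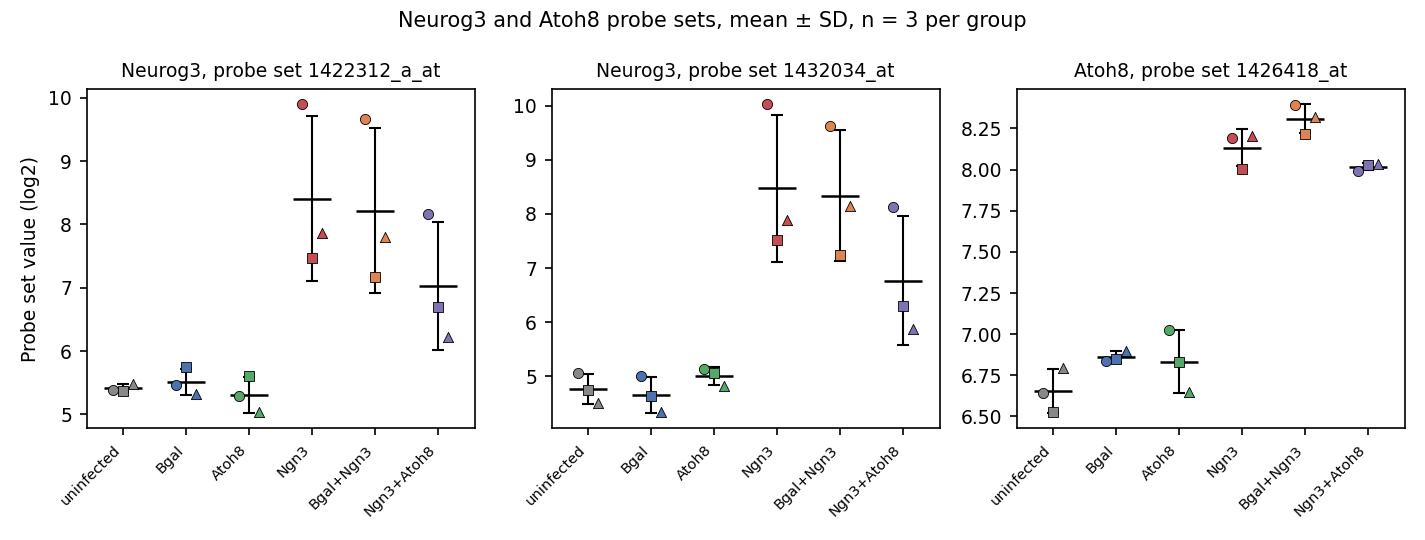
Probe set values (log2, vertical axis) of Neurog3 and Atoh8 in the 6 groups (horizontal axis); circles, squares and triangles are replicates 1, 2 and 3, and lines and bars are the mean ± SD (n = 3). Neurog3 is 8.41 in Ngn3 against 5.52 in Bgal on the brighter probe set, and Atoh8 is 6.83 in arrays labelled Atoh8 against 6.86 in Bgal.

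Bgal against uninfected cells asks which genes respond to 1 control adenovirus. Mitosis genes lay lower after infection, by a median of -0.33 log2 units, with 0 of 26 above 0 (camera adjusted p = 1.12e-25; adjusted p = 0.177 with an estimated correlation). Adjusted over the list alone, 15 of the 26 fell (23 with the replicate block), among them Ube2c, which marks cyclins for destruction (-0.44 ± 0.13, SE), and Aurkb, a kinase of chromosome segregation (-0.41 ± 0.12). Acinar markers had a median of 0.072, with 15 of 19 above 0 (adjusted p = 0.0206; adjusted p = 0.118 with an estimated correlation), and Spink1, a trypsin inhibitor of acinar cells, rose when adjusted over the list alone (0.72 ± 0.16). Cholesterol synthesis genes had a median of -0.10, with 4 of 18 above 0 (adjusted p = 0.0413; adjusted p = 0.952 with an estimated correlation), and 0 were called adjusted over the list alone. These named members were chosen after their values were seen.

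No gene was called by limma over all 18193 tested, and 708 had an unadjusted p under 0.05, where evenly spread p-values would give 910. This fit leaves the replicate differences in its spread (median residual SD 0.123 log2 units, against 0.104 with the block). A count under 910 therefore does not argue against a response. With the replicate block 0 genes were called as well, and 1586 had an unadjusted p under 0.05. The 3 smallest p-values were those of Cyp11a1, the enzyme of the opening step of steroid synthesis (0.39 ± 0.08), Spink1 (0.72 ± 0.16) and Map3k10, a mixed-lineage kinase (-0.39 ± 0.09), each with an adjusted p of 1.00. With the block hypoxia and glycolysis genes passed as well (median -0.16, adjusted p = 7.85e-05 against 0.0515 without it; adjusted p = 0.637 with an estimated correlation and the block). The acinar call ended without uninfected replicate 3 (adjusted p = 0.0708) and without replicate 2 (0.116) or 3 (0.0593) as a whole, and the cholesterol call ended without Bgal replicate 1 (0.142) or 2 (0.181) or uninfected replicate 2 (0.0695) or 3 (0.241), and without replicate 2 (0.0786) or 3 (0.168) as a whole.

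Bgal+Ngn3 against Ngn3 asks what a second, control virus adds to Ngn3. p53 target genes, which answer DNA damage, had a median of 0.089 log2 units with 21 of 24 above 0 (camera adjusted p = 0.00238; adjusted p = 0.309 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.13 with 0 of 21 above 0 (adjusted p = 0.0446; adjusted p = 0.978 with an estimated correlation). Adjusted over the list alone, 0 members of either list were called, and Mdm2, the ligase that degrades p53, differed by 0.21 ± 0.18 (SE), a member chosen after its value was seen. Mitosis genes passed only with the replicate block (median -0.079, mean above 0 in 1 of 3 pairs, adjusted p = 0.045 against 0.130 without it; adjusted p = 0.861 with an estimated correlation and the block).

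No gene was called by limma with or without the block; 536 genes had an unadjusted p under 0.05 without it and 996 with it. The 3 smallest p-values were those of 2810408I11Rik (-0.40 ± 0.07), Igfbp5, a binding protein of insulin-like growth factors (-0.31 ± 0.06), and 5730419F03Rik (-0.36 ± 0.08), each with an adjusted p of 1.00. Both list calls ended without Ngn3 replicate 2 (p53 targets 0.122, hypoxia genes 0.754) and without Bgal+Ngn3 replicate 3 (0.429 and 0.761). Without replicate 3 as a whole both ended too (0.103 and 0.319). The hypoxia call also ended without Bgal+Ngn3 replicate 1 (0.776), and its median was 0.037 without Ngn3 replicate 2.

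Atoh8 against Bgal asks what the Atoh8 virus does without Ngn3, at 1 virus on each side. p53 target genes were higher in arrays labelled Atoh8, by a median of 0.18 log2 units with 20 of 24 above 0 (camera adjusted p = 5.02e-08; adjusted p = 0.0181 with an estimated correlation), and the list mean was higher in 3 of 3 replicate pairs. Adjusted over the list alone, 3 members rose (9 with the replicate block): Mdm2, the ligase that degrades p53 (0.59 ± 0.18, SE), Gtse1, a regulator of p53 during the cell cycle (0.45 ± 0.14), and Phlda3, an inhibitor of Akt signalling (0.42 ± 0.09). Over all genes their adjusted p was 0.998, 0.998 and 0.603; the 3 were chosen after their values were seen. Mitosis genes had a median of 0.11 with 24 of 26 above 0, but a higher mean in only 2 of 3 pairs (adjusted p = 1.04e-04; adjusted p = 0.963 with an estimated correlation), with 0 called adjusted over the list alone and 1 with the block. The p53 call with an estimated correlation ended with the replicate block (adjusted p = 0.0681).

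No gene was called by limma without the block, and 804 had an unadjusted p under 0.05. Chrnb1, a subunit of the muscle acetylcholine receptor (0.63 ± 0.10), Kank3, an ankyrin-repeat protein (0.44 ± 0.07), and Dglucy, a D-glutamate cyclase (0.44 ± 0.07), had the smallest p, each with an adjusted p of 0.0700. With the replicate block 19 genes were called, all higher in arrays labelled Atoh8, 8 of them by at least 1.5-fold, and 1624 had an unadjusted p under 0.05. The largest of the 19 besides Chrnb1 (blocked adjusted p = 0.00625) were Ptp4a3, a protein tyrosine phosphatase (0.88, blocked adjusted p = 0.0259), Mctp2, a calcium-binding membrane protein (0.74, 0.0483), Sulf2, a sulfatase that edits heparan sulfate (0.68, 0.0156), and Mybl1, a Myb-family transcription factor (0.62, 0.0156). Without Atoh8 replicate 3 the unblocked fit called 1 gene, Chrnb1 (adjusted p = 0.00575). The mitosis call ended without Bgal replicate 2 (adjusted p = 0.657) or replicate 2 as a whole (0.201); the infection comparison uses the same Bgal arrays with the opposite sign.

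Ngn3 against Bgal asks what Neurogenin 3 does at 1 virus on each side. The largest rises were in Insm1, a zinc-finger factor of endocrine progenitors, at 4.77 ± 0.42 log2 units or 27.4-fold (SE, n = 3 per group; adjusted p = 5.11e-06), and Iapp, the islet amyloid polypeptide of beta cells, at 4.66 ± 0.22 or 25.3-fold (adjusted p = 3.46e-09). Insm1 stood at 4.70 in Bgal, near the mean lower quartile of those arrays (4.64). Background was not tested, so the size of its fold is uncertain. The same holds for St18, named below, which stood lower still in Bgal, at 4.23. Ttyh1, a membrane protein of neural cells, rose by 4.17 ± 0.30, Chgb, chromogranin B of secretory granules, by 4.08 ± 0.39, Ifitm1, an interferon-induced membrane protein, by 3.44 ± 0.28, Epb42, a protein of the red cell membrane skeleton, by 3.34 ± 0.48, and St18, a zinc-finger factor, by 2.87 ± 0.48. The largest falls were in Sprr2h, a small proline-rich protein of squamous epithelium (-2.85 ± 0.38, 7.21-fold lower), and in Mmp13 (-2.57 ± 0.36) and Mmp10 (-2.40 ± 0.39), both secreted matrix metalloproteinases. Egr3, an immediate early transcription factor (-2.28 ± 0.44), Anxa10, an annexin (-2.18 ± 0.25), Havcr2, an immune checkpoint receptor (-2.09 ± 0.38), Plek, a protein kinase C substrate of blood cells (-2.05 ± 0.41), and Gsta2, a glutathione transferase (-2.01 ± 0.25), followed.

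In all, limma called 2229 of 18193 genes (12.3%), of which 1298 rose and 931 fell; 922 changed by at least 1.5-fold (558 rose, 364 fell). In 2212 of the 2229, the 3 Ngn3 arrays lay all above or all below the 3 Bgal arrays; over all genes 30.5% did, against 10% by chance. With the replicate block 4096 genes were called (2267 rose, 1829 fell), including all 2229. The count fell to 988 without Ngn3 replicate 1, 1267 without Bgal replicate 2 and 1483 without Bgal replicate 1, and to 673 or 794 without replicate 1 or 3 as a whole. Without replicate 3, St18 (adjusted p = 0.0564), Neurog3 (0.0723), Egr3 (0.0574), Havcr2 (0.0981) and Plek (0.0818) were not called, and Plek was not called without replicate 1 (0.0664). Here and below, fits with arrays or replicates left out have no block, so replicate differences stay in their spread. With all arrays and the block, limma adjusted p was 8.75e-06 for St18, 9.44e-05 for Neurog3, 1.19e-06 for Egr3, 2.59e-07 for Havcr2 and 4.72e-07 for Plek. The probe set that measured Sprr2h is shared by several transcripts, and 2 of 3 other probe sets of Ttyh1 rose (5.49 and 4.21) while its last (0.15, adjusted p = 0.574) and the other of Egr3 (-0.19, adjusted p = 0.214) were not called. That of St18 rose less (1.09, adjusted p = 0.0167).

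**Figure D3:**
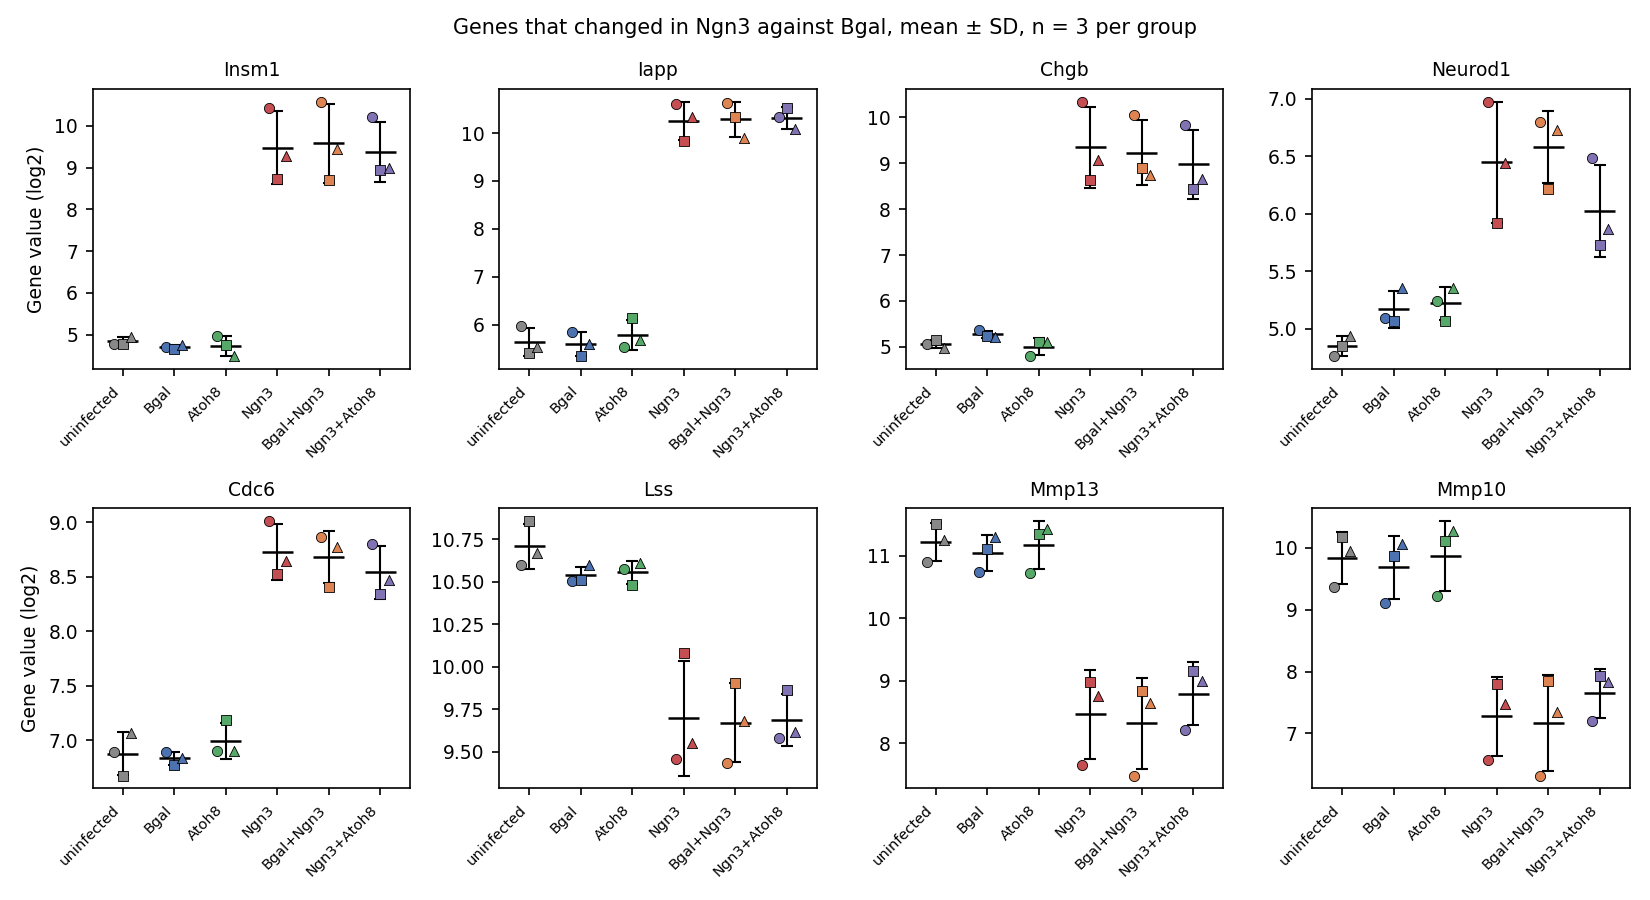
Values of 8 genes (log2, vertical axis) that changed in Ngn3 against Bgal, in the 6 groups (horizontal axis); circles, squares and triangles are replicates 1, 2 and 3, and lines and bars are the mean ± SD (n = 3). Insm1 is 9.48 in Ngn3 against 4.70 in Bgal, and Mmp13 is 8.47 against 11.04.

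Some endocrine genes rose with Ngn3. Of 18 measured endocrine transcription factors 6 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 7.19e-05, adjusted p = 0.346 with an estimated correlation), led by Insm1, St18, Pax4, a repressor needed for beta cells (1.29 ± 0.29, SE), and Neurod1, which acts downstream of Neurog3 (1.28 ± 0.22). Of 29 islet hormone and secretory genes 9 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 1.92e-05, adjusted p = 0.228 with an estimated correlation), led by Iapp, Chgb and Pcsk1, a prohormone convertase (1.88 ± 0.39). Without Ngn3 replicate 1 the counts were 3 factors and 5 secretory genes, and Pax4 was not called (adjusted p = 0.0609). Without Bgal replicate 2 the secretory count was 5. Without replicate 3 as a whole the counts were 2 and 4, and Pax4 (0.165) and Pcsk1 (0.0719) were not called; Pax4 was not called without replicate 1 either (0.138).

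Genes of DNA replication and mitosis rose almost throughout. Of 26 S phase and replication genes 25 rose and 0 fell (26 and 0 adjusted over the list alone), with a median of 1.10 log2 units (camera adjusted p = 4.12e-32; adjusted p = 0.0626 with an estimated correlation). Cdc6, which loads the replicative helicase, rose by 1.89 ± 0.15 (SE), Mcm5, a helicase subunit, by 1.54 ± 0.18, and Cdc45, which activates the helicase, by 1.48 ± 0.16. All 26 mitosis genes rose, also adjusted over the list alone, with a median of 0.93 (adjusted p = 7.00e-34; adjusted p = 0.0699 with an estimated correlation). Melk, a mitotic kinase, rose by 1.17 ± 0.16, Ncapg, a condensin subunit, by 1.17 ± 0.12, and Ttk, a kinase of the spindle checkpoint, by 1.15 ± 0.13. Without replicate 1 as a whole 16 of the 26 S phase genes rose.

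Most cholesterol synthesis genes and a few hypoxia and glycolysis genes fell. Of 18 cholesterol synthesis genes 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.59 log2 units (camera adjusted p = 5.61e-16; adjusted p = 0.09995 with an estimated correlation). Mvd, mevalonate decarboxylase, fell by 0.87 ± 0.14 (SE), Lss, lanosterol synthase, by 0.84 ± 0.14, and Cyp51, lanosterol demethylase, by 0.74 ± 0.12. Of 21 hypoxia and glycolysis genes 4 fell and 0 rose (4 and 0 adjusted over the list alone, 17 and 0 with the replicate block), with all 21 below 0 and a median of -0.45 (adjusted p = 1.53e-05; adjusted p = 0.510 with an estimated correlation), and with the replicate block 13 fell. The 4 were Ero1a, an oxidase of the endoplasmic reticulum (-1.29 ± 0.35), Pfkp, a phosphofructokinase (-0.86 ± 0.26), Car9, a carbonic anhydrase (-0.74 ± 0.09), and Bnip3, a mitophagy receptor (-0.56 ± 0.15). Without replicate 1 or 3 as a whole 8 or 3 cholesterol genes fell, and Mvd, Lss and Cyp51 were not called without replicate 3 (adjusted p = 0.0633, 0.0753 and 0.0664). Ero1a, Pfkp and Bnip3 lost their calls without Ngn3 replicate 1 (adjusted p = 0.145, 0.202 and 0.139), Ngn3 replicate 3 (0.0562, 0.136 and 0.0887) or Bgal replicate 2 (0.0793, 0.127 and 0.0782), Pfkp and Bnip3 without Bgal replicate 1 (0.0999 and 0.0870), and Ero1a and Pfkp without Bgal replicate 3 (0.0519 and 0.0659). The count of falls was 1 without Ngn3 replicate 1 or 3 or Bgal replicate 2, 2 without Bgal replicate 1 or 3, 7 without Ngn3 replicate 2, and 1, 8 and 1 without replicates 1, 2 and 3.

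Some stress and antiviral genes changed. Of 23 unfolded protein and amino acid stress genes 9 rose and 0 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0170, adjusted p = 0.0699 with an estimated correlation), among them the endoplasmic reticulum proteins Sdf2l1 (0.55 ± 0.16, SE), Creld2 (0.52 ± 0.12) and Herpud1 (0.52 ± 0.08). Ddit3 (-0.72 ± 0.26) and Atf3 (-0.59 ± 0.22) fell adjusted over the list alone but were not called over all genes (limma adjusted p = 0.0904 and 0.0919). With the replicate block 11 members of this list rose and 4 fell. Of 35 interferon and antiviral genes 4 rose and 3 fell (5 and 3 adjusted over the list alone; adjusted p = 0.0347, adjusted p = 0.510 with an estimated correlation). Ifit2, an antiviral RNA-binding protein, rose by 1.04 ± 0.21 and Psmb8, an immunoproteasome subunit, by 0.81 ± 0.10, while H2-K1, a class I antigen-presenting molecule, fell by 0.49 ± 0.12. The other probe set of Psmb8 was not called (0.11, limma adjusted p = 0.396). Of the other probe sets of H2-K1, 1 was called (-0.48, adjusted p = 0.0392) and the rest were not (-0.12 and -0.21, adjusted p = 0.671 and 0.182). With the block 8 interferon and antiviral genes rose and 3 fell. Without Ngn3 replicate 1 or Bgal replicate 2 only 1 unfolded protein gene rose and 0 interferon genes fell; 5 and 3 unfolded protein genes rose without Bgal replicates 1 and 3. The interferon call ended without Ngn3 replicate 1 (adjusted p = 0.156), Bgal replicate 3 (0.0535) or replicate 1 as a whole (0.124), and the unfolded protein call without replicate 2 (0.126). Sdf2l1, Creld2 and H2-K1 were not called without Ngn3 replicate 1 (adjusted p = 0.164, 0.0592 and 0.0746) or Bgal replicate 2 (0.158, 0.0505 and 0.0823), Sdf2l1 and H2-K1 without Ngn3 replicate 3 (0.0717 and 0.0565), and Sdf2l1 without Bgal replicate 3 (0.0597).

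The other 13 lists did not pass the camera test for Ngn3 (adjusted p from 0.0618 to 0.954), though members moved. Among 22 duct markers 5 rose and 4 fell (5 and 5 adjusted over the list alone), with Prom1, a membrane glycoprotein, up by 1.61 ± 0.19 (SE), Krt7, a duct keratin, up by 1.00 ± 0.09 and Muc1, a surface mucin, at -1.24 ± 0.17. Among 28 neuronal genes 3 rose, led by Map2, a dendritic microtubule protein (2.64 ± 0.24), and 0 fell. Other probe sets of Map2 changed less, by 1.08, 0.69 and 0.046, and the last was not called (limma adjusted p = 0.855). Among 25 inflammatory NF-kappaB genes 2 rose, Ccl2 (2.05 ± 0.12) and Cxcl15 (1.26 ± 0.21), both chemokines, and 4 fell (2 and 5 adjusted over the list alone); the list's median was 0.013, while camera ranked it downward. Among 22 TGF-beta and BMP response genes 1 rose, the pseudoreceptor Bambi (1.61 ± 0.35), and 4 fell, led by Grem1, a BMP antagonist (-1.54 ± 0.17). Among 24 p53 target genes 5 rose, led by Eda2r, a receptor of the tumour necrosis factor family (1.11 ± 0.18), and 1 fell (6 and 1 adjusted over the list alone). Among 29 Notch pathway genes 2 rose and 2 fell (median -0.0023, mean 0.0028), and among 26 basic helix-loop-helix factors and partners 2 rose and 0 fell; Hes6, a member of both lists, rose by 1.15 ± 0.24. Heat shock genes showed 4 rises and 2 falls among 16 (4 and 3 adjusted over the list alone), with Hsph1, a chaperone, up by 0.59 ± 0.12. Among 22 cytoskeleton and SRF target genes 0 rose and 2 fell, led by Tagln2, an actin-binding protein (-0.42 ± 0.12).

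Markers of other cell types moved in single genes. Among 19 acinar markers 2 rose, led by Clps, pancreatic colipase (1.72 ± 0.38, SE), and 2 fell, with a median of -0.009 and a mean of 0.065. Among 23 mesenchymal genes 2 rose, led by Tgfbi, a matrix protein (0.56 ± 0.13), and 0 fell. Among 13 leukocyte markers Cd68, a lysosomal glycoprotein of macrophages, fell (-1.05 ± 0.25) and Lyz2, a lysozyme, rose (0.71 ± 0.17), and among 14 endothelial markers 1 fell, Flt1, a receptor of vascular growth factor (-1.13 ± 0.30). Except where given, counts adjusted over the list alone were those over all genes. With the replicate block the TGF-beta list (2 rose, 8 fell; adjusted p = 0.0139) and the cytoskeleton list (1 rose, 9 fell; adjusted p = 0.0105) passed at the preset correlation but not with an estimated correlation (adjusted p = 0.196 and 0.240). The block also gave 6 rises of neuronal genes, 8 rises and 3 falls of p53 targets, 4 rises and 3 falls in each of the Notch and basic helix-loop-helix lists, and 4 rises and 4 falls of mesenchymal genes. Calls ended without Ngn3 replicate 1 for Tagln2 (adjusted p = 0.147), Tgfbi (0.0708), Cd68 (0.0772), Lyz2 (0.0748) and Flt1 (0.112), and without Bgal replicate 2 for Tagln2 (0.106), Cd68 (0.0647) and Flt1 (0.0840). They ended without Bgal replicate 3 for Tagln2 (0.0732), Tgfbi (0.0524) and Lyz2 (0.0502), and without Ngn3 replicate 3 for Tagln2 (0.0797) and Flt1 (0.0737). Clps (0.115) and Hes6 (0.104) were not called without replicate 3 as a whole, Hsph1 (0.0535) without replicate 1, and Bambi without either (0.123 without replicate 1, 0.101 without replicate 3).

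**Figure D4:**
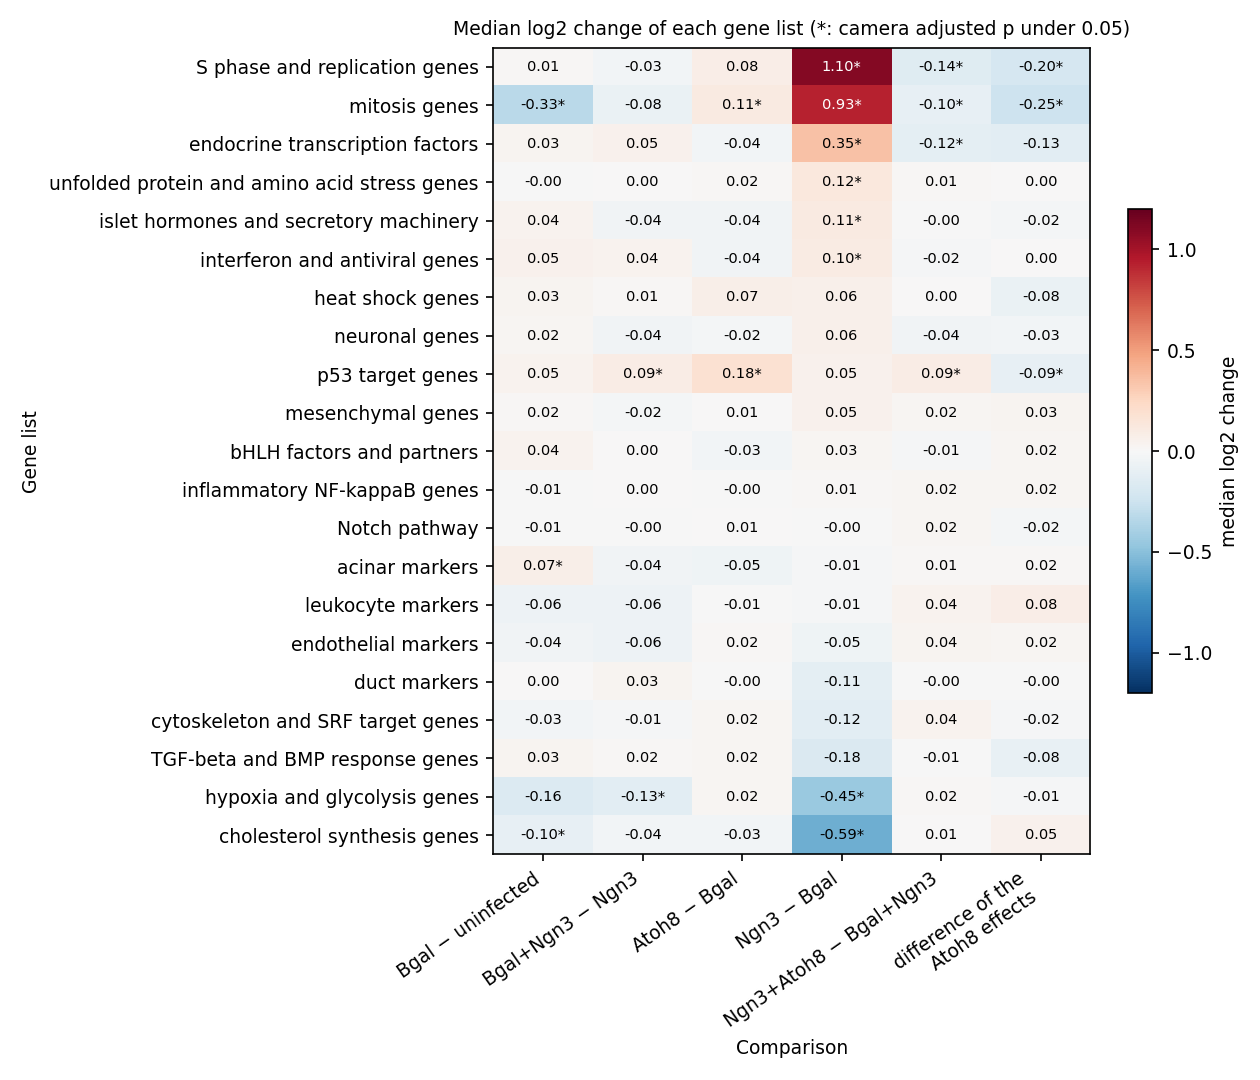
Median log2 change of the 21 gene lists (vertical axis) in the 6 comparisons (horizontal axis), coloured from blue (lower) to red (higher), with a star at a camera adjusted p under 0.05 at the preset correlation. S phase genes stand at 1.10 and mitosis genes at 0.93 in Ngn3 minus Bgal, and 1 star, p53 target genes in Atoh8 minus Bgal, also holds with an estimated correlation (adjusted p = 0.0181), but not with the replicate block added (adjusted p = 0.0681).

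Ngn3+Atoh8 against Bgal+Ngn3 asks what the Atoh8 virus adds in the presence of Ngn3, at 2 viruses on each side. S phase and replication genes were lower with Atoh8, by a median of -0.14 log2 units with 1 of 26 above 0 (camera adjusted p = 4.47e-06), as were mitosis genes (-0.10, 3 of 26 above 0, adjusted p = 1.33e-04) and endocrine transcription factors (-0.12, 4 of 18 above 0, adjusted p = 0.00881); each had adjusted p = 0.898 with an estimated correlation. The S phase and mitosis means were each lower in 2 of 3 replicate pairs and above 0 in 1, and the endocrine factor mean was lower in 3 of 3. p53 target genes were higher (0.091, 21 of 24 above 0, adjusted p = 0.00548; adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone, 0 members of these lists were called. Neurod1 differed by -0.56 ± 0.22 and Mcm4, a helicase subunit, by -0.18 ± 0.12 (SE), both chosen after their values were seen. The lower lists went with a lower Neurog3 signal in the same arrays (-1.18).

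No gene was called by limma without the block, and 304 had an unadjusted p under 0.05. Ivl, involucrin of squamous epithelium (0.93 ± 0.16, adjusted p = 0.409), Pcolce, an enhancer of procollagen processing (0.38 ± 0.09, adjusted p = 1.00), and Stfa2l1, a stefin-like protease inhibitor (-0.26 ± 0.07, adjusted p = 1.00), had the smallest p. With the block Ivl was called (adjusted p = 0.00522) and 674 genes had an unadjusted p under 0.05; Ivl was also called without Bgal+Ngn3 replicate 2 (0.0446) or Ngn3+Atoh8 replicate 3 (0.0427), and against Ngn3 as the control (0.0449). Without Bgal+Ngn3 replicate 1 the S phase (adjusted p = 0.176), mitosis (0.593) and endocrine factor (0.710) calls all ended and the endocrine median was 0.029. They also ended without replicate 3 as a whole (0.0565, 0.222 and 0.235), the mitosis call without replicate 1 (0.118) and the p53 call without replicate 2 (0.607). The mitosis call also ended without Bgal+Ngn3 replicate 3 (0.0675), the endocrine call without Ngn3+Atoh8 replicate 2 (0.481) or 3 (0.162), and the p53 call without Bgal+Ngn3 replicate 2 (0.962) or Ngn3+Atoh8 replicate 3 (0.1004).

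Genes that respond to Ngn3 were followed into the same comparison. The 1298 genes that rose with Ngn3 had a median of -0.035 log2 units when Atoh8 was added, with 66.8% below 0 against 51.3% of all genes (camera p = 4.56e-04; p = 0.535 with an estimated correlation). The 931 genes that fell with Ngn3 had a median of 0.025, with 60.2% above 0 (p = 0.0260; p = 0.650 with an estimated correlation). Without replicate 3 the medians were -0.017 (p = 0.728 at the preset correlation) and -0.022 (p = 0.106), and with the Neurog3 signal as a covariate they turned to 0.074 and -0.061, or 0.051 and -0.068 with the block too. With 0 genes called in Ngn3+Atoh8 minus Bgal+Ngn3, no member is singled out. The planned follow-up of Atoh8-responsive and infection-responsive genes had 0 genes to follow in the fit without the block.

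The difference between the effect of Atoh8 with Ngn3 and without it asks whether Ngn3 alters the response to Atoh8. Mitosis genes differed by a median of -0.25 log2 units (camera adjusted p = 6.77e-09), S phase and replication genes by -0.20 (adjusted p = 2.83e-06) and p53 target genes by -0.094 (adjusted p = 0.0251), and each had adjusted p = 0.580 with an estimated correlation. Ngn3 raises the mitosis and S phase lists, and the Neurog3 signal was lower in Ngn3+Atoh8 than in Bgal+Ngn3 (-1.18) in 3 of 3 pairs, so the difference does not separate Atoh8 from that signal. The p53 call ended without Bgal replicate 1 (adjusted p = 0.116) or 2 (0.0555), Atoh8 replicate 2 (0.0582) or 3 (0.183), Bgal+Ngn3 replicate 1 (0.0655) or 3 (0.301), Ngn3+Atoh8 replicate 2 (0.152), or replicate 3 as a whole (0.630). Adjusted over the list alone, 0 members of the 3 lists were called. No gene was called by limma with or without the block, and 463 and 959 genes had an unadjusted p under 0.05. Kank3 (-0.41 ± 0.10, SE), Elk1, an ETS-family transcription factor (-0.40 ± 0.10), and Zfp677, a zinc-finger protein (0.42 ± 0.11), had the smallest p, each with an adjusted p of 1.00.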

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

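The tests of virus load and of RNA quality for p53 target genes, the estimated correlation with a replicate block and the list tests with arrays left out were chosen only after the results were seen.

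Arrays labelled Atoh8 differed from their controls to another extent with and without Ngn3 in 3 gene lists, by a test of the difference at the preset correlation. The Neurog3 signal was also lower in Ngn3+Atoh8 than in Bgal+Ngn3 (-1.18), and Ngn3 raises the mitosis and S phase lists, so an effect of Atoh8 is not separated from that signal. The median difference was -0.25 log2 units for 26 mitosis genes (adjusted p = 6.77e-09), -0.20 for 26 S phase and replication genes (adjusted p = 2.83e-06) and -0.094 for 24 p53 target genes (adjusted p = 0.0251). Each had adjusted p = 0.580 with an estimated correlation, 0.478 with that correlation and the block, and fry adjusted p from 0.935 to 0.938. The mitosis and S phase calls held without each of the arrays and replicates in turn, in 15 of 15 fits, with medians from -0.36 to -0.12 and from -0.36 to -0.11. The p53 call held in 7 of 15 and ended without Bgal replicate 1 (adjusted p = 0.116) or 2 (0.0555), Atoh8 replicate 2 (0.0582) or 3 (0.183), Bgal+Ngn3 replicate 1 (0.0655) or 3 (0.301), Ngn3+Atoh8 replicate 2 (0.152), or replicate 3 as a whole (0.630). For single genes the real split called 0, as did the highest other of 100 drawn of 200 splits of these arrays; with 0 calls all 100 give as many whatever the data, so these splits decide nothing.

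Splits of 3 against 3 arrays number 10, too few for a share under 0.05. For Ngn3 minus Bgal the real split called 2229 genes and the highest other 0, and 1 of the 10 splits gave as many. For Bgal minus uninfected, Bgal+Ngn3 minus Ngn3, Atoh8 minus Bgal and Ngn3+Atoh8 minus Bgal+Ngn3 the real split called 0 and the highest other 0, so 10 of 10 give as many whatever the data, and these splits decide nothing. Among the 4 splits of Ngn3 and Bgal arrays that part all 3 replicate pairs, the other 3 called 0.

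p53 target genes had a mean 0.18 log2 units higher in arrays labelled Atoh8 than in Bgal, and the call at the preset correlation held in 9 of 9 fits with arrays left out but ended with an estimated correlation and the block (adjusted p = 0.0681). RNA quality as the whole cause is argued against, though a part stays open: with the beta-actin 3' minus 5' difference as a covariate the mean was 0.18 (fry in the fit of all arrays, n = 18, p = 0.00555), and with the covariate and the block 0.13 (p = 0.0112, against 0.00151 without the covariate). That difference was lower in Atoh8 than in Bgal in 3 of 3 pairs without separating the groups, and the covariate had an unadjusted p under 0.05 for 1236 genes with the block and 2417 without it but 0 limma calls; what would count here was reworded after values were seen, and a wording that asked for such calls would leave RNA quality open. More virus taken up by these cells may account for part of the shift, and the test does not exclude all of it. A second control virus moved the list by 0.088 in arrays given Ngn3, and a single one by 0.041 over uninfected cells. Replicate pairs ranged from 0.17 to 0.20 for Atoh8, 0.030 to 0.14 for a second virus and 0.013 to 0.089 for a single one. The Ngn3 virus moved the list mean by 0.16 over the same Bgal arrays, with pairs from 0.082 to 0.25. The list did not pass the camera test for Ngn3, but a higher list mean was not particular to Atoh8. The difference of 0.097 between Atoh8 and a second virus had p = 0.167 by fry in the fit of all arrays (n = 18, and 0.140 with the block), which does not decide. What would count for that explanation was reworded after these values had been seen. It went from a fry p of 0.05 or more to a difference at or below 0. The earlier wording would have counted the observed p in its favour. Virus load therefore cannot be told apart from an effect of Atoh8, which stays open. The Atoh8 probe set does not check the label, so that effect rests on the label and was not tested separately.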

How the results depend on the processing

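The Neurog3 covariate, the estimated correlation with the block, fry with the block, and list tests with arrays left out were chosen only after the results were seen. Counts of 0 for infection, a second virus and the difference of Atoh8 effects stayed at 0 in every alternative run. Atoh8 minus Bgal went from 0 genes to 3 (Chrnb1, Dglucy and Kank3) without the dimmest 40% of genes, where fewer genes are tested, to 19 with the replicate block, and to 0 to 1 with an array or replicate left out. Ngn3 minus Bgal went from 2229 to 4096 with the replicate block, 922 at a fold of 1.5 or more, and 673 to 2444 with an array or replicate left out, where fewer arrays are fitted. Ngn3+Atoh8 minus Bgal+Ngn3 went from 0 to 1 (Ivl) with the replicate block, to 1 with Ngn3 in place of Bgal+Ngn3 as control, and to 0 to 1 with arrays left out. Quantile normalization and centring moved the share of rises among Ngn3 calls from 58.2% to 56.5% and 54.4%.

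The median of genes that rose with Ngn3, -0.035 in Ngn3+Atoh8 minus Bgal+Ngn3, was -0.035 with an estimated correlation (p = 0.535), 0.074 with a Neurog3 covariate, 0.051 with that covariate and the replicate block, and -0.086 to -0.017 with a replicate left out (p = 0.728 without replicate 3). For genes that fell, 0.025 became 0.025 with an estimated correlation (p = 0.650), -0.061 with the covariate, -0.068 with covariate and block, and -0.022 to 0.077 with a replicate left out, the sign turning without replicate 3 (p = 0.106); the cause of that turn was not tested. Genes called for Atoh8 with the same sign in Ngn3+Atoh8 minus Bgal+Ngn3 numbered 0, 3 without the dimmest genes and 18 with the replicate block. Tests with an estimated correlation were not run for the empty Atoh8 and infection lists. List calls went from 22 to 1 with an estimated correlation, 0 with that and the replicate block, 7 with fry, 14 with fry and the replicate block, and 16 to 36 with arrays left out (36 without Bgal+Ngn3 replicate 2); the cause was not tested.

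Of 84 named calls for Ngn3, 84 held with the block, and it changed no other named call but those of the Atoh8 genes and Ivl, most of which are named because the block called them. With arrays or replicates left out, in fits without the block, 585 of these tests held and 171 lost the call, with 0 reversed. Pfkp, Cela1, Tcf12 and Tpm2 were lost most often, each in 7 fits. Quantile normalization lost 2, centring 1 and the trended variance 3. Among other probe sets of these genes, 46 were called the same way, 34 were not called and 2 had the opposite sign, 1 of Sparc (-0.079, adjusted p = 0.783) and 1 of Cdc45 (-0.12, adjusted p = 0.633). Signal over background is not known from the table, so small changes of dim genes are limited by compression of the log2 scale.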

Other observations

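The tests of gene families by name, of the Neurog3 covariate, of replicate differences, of the correlation with Neurog3, also by run, and of the 19 genes called with the block were chosen only after the results were seen; those of array scaling and of other splits were planned.

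Some genes that share a symbol stem changed with Ngn3 in families the fixed lists cover only in part. Of 541 families tested with camera, 27 passed, 24 upward and 3 downward, and 0 passed with an estimated correlation. Beta protocadherins, clustered adhesion proteins of neurons, rose in 8 of 22 measured members (median 0.42 log2 units, adjusted p = 2.30e-05; adjusted p = 0.992 with an estimated correlation), with Pcdhb9 at 1.65 ± 0.42 (SE, n = 3 per group) and Pcdhb12 at 1.29 ± 0.28. Nucleoporins rose in 7 of 19 (median 0.25, adjusted p = 4.59e-05; adjusted p = 0.777 with an estimated correlation), with Nup85 at 0.78 ± 0.14. Clamp loader subunits rose in 5 of 5 (median 0.67, adjusted p = 5.83e-05; adjusted p = 0.777 with an estimated correlation), with Rfc3 at 0.94 ± 0.23.

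Downward, annexins fell in 6 of 11 (median -0.32, adjusted p = 8.23e-05; adjusted p = 0.899 with an estimated correlation), with Anxa10 at -2.18 ± 0.25 and Anxa8 at -0.85 ± 0.14. Mucins fell in 4 of 10 (median -0.25, adjusted p = 0.00665; adjusted p = 0.777 with an estimated correlation), with Muc1 at -1.24 ± 0.17 and Muc5b, a secreted mucin, at -1.03 ± 0.20. Small proline-rich proteins fell in 4 of 9 (median -0.23, adjusted p = 0.0499; adjusted p = 0.992 with an estimated correlation), with Sprr2h at -2.85 ± 0.38 and Sprr1a at -0.64 ± 0.20. Members of such families can share probes, and no family named here changed sign under quantile normalization or centring.

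The 19 genes called for Atoh8 with the block were followed where no array is shared. In Ngn3+Atoh8 minus Bgal+Ngn3, 18 of 19 lay above 0 (median 0.18, camera p = 6.40e-11; p = 2.97e-04 with an estimated correlation), and in Bgal+Ngn3 minus Ngn3, which adds a control virus, 16 of 19 did (median 0.10, camera p = 6.99e-06; p = 0.00477 with an estimated correlation).

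Genes that rose with Ngn3 were lower in Ngn3+Atoh8 than in Bgal+Ngn3, by a median of -0.035 log2 units. The median stayed below 0 after quantile normalization (-0.030) and after centring (-0.051). RMA had already normalized the arrays together, so these further scalings cannot exclude array scaling as the cause. A lower Neurog3 signal in the Ngn3+Atoh8 arrays is a candidate explanation: with that signal as a covariate and the block the median was 0.051, and 0.058, 0.049 and 0.069 without replicates 1, 2 and 3. The covariate cannot say whether Atoh8 or the dose of the Ngn3 virus lowered Neurog3, and chance stays open. Neurog3 was itself called as rising with Ngn3, and its probe sets may read the cells' own transcript. The covariate may thus be part of the response it adjusts for, so the turn above 0 does not decide. Of the 10 splits of these 6 arrays, too few for a share under 0.05, 8 gave a median as far from 0 as the real -0.035 (highest other 0.196), and 7 did for the genes that fell (0.025; highest other -0.146); among the 4 that part all 3 replicate pairs the numbers are 2 (highest other -0.057) and 2 (highest other 0.040).

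The Ngn3 response was larger in replicate 1 than in replicate 2: the mean of the genes that rose was higher by 0.31 log2 units in Ngn3, 0.33 in Bgal+Ngn3 and 0.25 in Ngn3+Atoh8, against 0.13 in uninfected, 0.03 in Bgal and 0.02 in Atoh8 arrays. A replicate difference unrelated to Ngn3 cannot be told apart as a part of this. The largest difference without Ngn3 was 0.510 of the smallest with it, just above a share of 0.5 set after values were seen. Each difference is between single arrays, so a share under 0.5 would not have excluded such a part either. A difference in Neurog3 level may contribute: over the 9 arrays with Ngn3 that signal correlated with the mean of the other genes that rose (r = 0.868, exact permutation p = 0.00170; rho = 0.867, permutation p = 0.00451), the only relation of this kind computed, over genes picked from some of the same arrays. Neurog3 itself rose with Ngn3, so its signal may be part of the response and not a measure of dose. Without Ngn3 replicate 1 and Bgal+Ngn3 replicate 1, the arrays farthest from the median, r was 0.640 (exact permutation p = 0.122) and rho 0.714 (p = 0.0881). With 7 arrays the relation stays open. Those p-values take the 9 arrays as exchangeable, but they come from 3 runs: within runs r was 0.718 (exact permutation p = 0.148), and exchanging whole runs cannot give a p under 0.167, which it gave; a biological difference between runs was not tested.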
